A study of Homo sapiens with 12 samples.

How the data were processed

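The data were 1 deposited table of bulk RNA sequencing with 35162 genes in rows and 40 columns. Per the labels' protocol, polyadenylated RNA was isolated, fragmented, reverse-transcribed and sequenced as paired ends. The same protocol speaks of adipose material although the samples are a cell line, so how far it describes these libraries is uncertain. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0, StringTie 1.3.0 and the mouse build mm8, with no role for any of them. How reads were assigned to genes and how FPKM was computed is not given in the sources used here. Per the file headers, the authors gave each gene an identifier, a name, a chromosome, a strand, start and end positions, functional terms, and 1 FPKM and 1 count for each of 12 libraries.

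The 12 samples were grouped by their titles into control, CCL17, and CCL17 with C-021, with 4 samples each. The libraries of the table are headed by the letters A, B and C, which match no label. The 24 columns of values per library could not be assigned to a sample or a group and entered no result. The number of libraries per letter equals the number of samples per group, but this does not say which letter is which group. The planned comparisons of the groups were therefore not run. For these, a linear model on log FPKM was planned, or a quasi-likelihood test if the counts were whole numbers. Whether they were was not checked. Also planned were tests for reversal of the response by the inhibitor and for a direction shared by the treated groups. Set tests on 40 gene lists and enrichment tests of functional terms were planned too. A test for any difference among the 3 groups and a look at sample structure do not require knowing which letter is which group. They were left out because unassigned columns were not used. Because no values were used, no depth, precision, error or adjusted p is given. The rule for naming genes asked for the most changed genes, for changed members of the lists and for 12 genes of interest. Only the last part could be applied.

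The annotation columns were compared with GENCODE 29 (GRCh38) in Python 3.11.15 with pandas 2.3.3. Identifiers were matched without their version. A gene was counted as placed alike when chromosome and strand were the same and the positions overlapped by at least 1 base. The counting was tested on simulated genes that were renamed, taken off their chromosome or shifted far beyond their own position. Small shifts were not simulated. Gene lists were matched by symbol. An older symbol in a list was also looked up under its current symbol where a RefSeq gene table led to a single one. Older names in the deposited table were not looked up for current list symbols. A list member without a row can therefore reflect a difference in naming. Gene positions are those of the deposited table, counted from 1. The functional terms were not used, since no comparison gave a set of genes to test for enrichment. Terms were present for 15685 genes for GO, 6823 for KEGG and 7077 for Reactome, and the cells of a further 2214, 16 and 2398 genes had been removed.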

Results

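RNA was sequenced from 12 samples of QBC-939, a cell line that the labels assign to human cholangiocarcinoma, a cancer of the bile duct. The identity and tissue of origin of the line were taken from the labels and not checked here. The sample titles gave 3 groups with 4 replicates each. One group was the control, one received CCL17, and one received CCL17 together with C-021. CCL17 is a secreted chemokine whose receptor is CCR4, and C-021 is a small molecule that blocks CCR4. The stated purpose was to follow how gene expression in these cells responds to the chemokine and to the inhibitor. Doses, exposure times and the origin of the replicates (separate cultures or not) were not given in the labels.

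The design implies 3 comparisons, namely CCL17 against control, CCL17 with C-021 against CCL17 alone, and CCL17 with C-021 against control. None of them was made. The deposited table gives 12 libraries under 3 letters, A, B and C, with 4 numbered libraries for each letter. No title, description, protocol or series text used here says which letter stands for which group. The order of the letters is not evidence of the groups, and neither are the expression values, so the 24 columns of values per library (12 headed FPKM and 12 headed count) were left unused. Values per library could have been given under the letters alone, but columns that cannot be matched to a labelled sample were not used at all, by a rule set before the data were examined. No expression level, sequencing depth or fold change is reported, and no statement is made about whether any gene responded to CCL17 or to C-021.

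The table itself held 35162 genes, each with its own human Ensembl identifier. GENCODE 29, a human gene annotation on the GRCh38 build, contained 33358 of these identifiers (94.9%). By its gene types, 16944 of the 35162 genes (48.2%) were protein-coding. That total includes the 1804 genes (5.1%) not in GENCODE 29, whose type is not known here. Processed pseudogenes made up 3985 genes, antisense transcripts 3395 and long intergenic non-coding RNAs 3060. Chromosome 1 held 3521 of the genes and the mitochondrial genome 37. Of the gene names, 49 stood on more than 1 row, among them Y_RNA with 235 rows.

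The genes closest to the question were looked up by name. CCR4, the receptor of CCL17, was listed as ENSG00000183813 on chromosome 3 from position 32951644 to 32956349 on the plus strand. CCR8, a related chemokine receptor, was listed as ENSG00000179934 on chromosome 3 from 39329709 to 39333680 on the plus strand. CCL22, the other chemokine ligand of CCR4, was listed as ENSG00000102962 on chromosome 16 from 57358783 to 57366189 on the plus strand. GENCODE 29 annotates all 3 as protein-coding genes, and for each of them it gives a different start or end than the table. CCL17 was not among the rows analysed here. The proliferation marker MKI67 and the epithelial genes CDH1, EPCAM, KRT7 and KRT19 were listed, as were the mesenchymal genes CDH2 and VIM and the immune checkpoint ligand CD274. A listing gives no expression level, and whether a gene needed to be detected to have a row was not tested. The lack of a row for CCL17 is therefore not evidence about its expression.

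Gene lists had been fixed before the data were examined, and 22 of the 40 lists had a row for every member. Those complete lists included the 55 genes of the G2 and M phases of the cell cycle, the 47 S phase genes, the 36 epithelial junction and keratin genes, the 44 interferon response genes and the 37 genes for invasion proteases and adhesion. The list of chemokine genes had rows for 14 of its 16 members, with none for CCL17 and ACKR1. The list of mesenchymal genes had rows for 37 of its 39 members and the list of NF-kB targets and inflammatory cytokines for 36 of 37. Among the lists of cell type markers, rows were present for 24 of 27 biliary epithelial, 15 of 21 hepatocyte, 17 of 22 cervical and Mullerian, 13 of 15 fibroblast, 14 of 24 leukocyte and 9 of 12 endothelial markers. These counts describe the rows analysed here, and no list was tested for a change. The share of all annotated genes with a row was not computed, so the marker counts are not evidence of cell type.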

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

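Other settings for the expression comparisons (pseudocount, filter, scaling, weights, samples left out, other tests) were not run, because the libraries could not be assigned to groups. No paired analysis was possible because pairing samples between control, CCL17 and CCL17 with C-021 needs columns assigned to those groups. Nothing in the labels says that a shared number marks a shared culture or day, so such a key alone would not support pairing. A comparison among the unnamed letters, with the library number as a block, could have been fitted and was left out by choice, since unassigned columns were not used. The single setting that was varied concerns gene positions and was chosen after seeing the data. Of the shared identifiers, 99.98% overlapped the GENCODE 29 gene on the same chromosome and strand, and 55.2% had identical start and end positions. The cause of the differing ends was not tested.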

Other observations

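The test on chromosome names was chosen after the table had been seen. The submitters' processing notes name the mouse build mm8 for a human cell line. A table made on that build would have no gene on chromosomes 20, 21 and 22, which the mouse lacks, but 2277 of the 35162 genes lay there. For a human build other than GRCh38, only overlap with GRCh38 itself was measured. Of the 33358 identifiers shared with GENCODE 29, 99.98% overlapped the GRCh38 gene of the same identifier. All 35162 identifiers were human, so a table with genes on these chromosomes was to be anticipated from the identifiers alone. The chromosome count therefore adds little to the identifiers, and both argue against mm8 as the source of the gene positions. For the 18427 shared identifiers (55.2%) with identical start and end, the positions are those of GRCh38. These identical positions argue against another human build as the source for those genes. No other human build was compared, so the overlap that one would give is not known here. A candidate explanation is that the notes were carried over from another study, which was not tested here.

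A key from the letters A, B and C to the 3 groups would open the comparisons. Which group a difference between letters belongs to, and its direction, cannot be stated without that key. Whether CCR4 was detected, or whether any gene differed among the unnamed letters, was not examined.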
